A study of Homo sapiens with 2 samples.

How the data were processed

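RNA bound by the RNA-binding protein HNRPA2B1 (current symbol HNRNPA2B1) was profiled by HITS-CLIP in MDA-MB-231, an established human breast cancer cell line. In HITS-CLIP, ultraviolet light crosslinks protein to RNA in living cells, the protein is immunoprecipitated, and the RNA that stays attached is sequenced. Per the labels' protocols, cells at 50% confluency were transfected with a tagged form of the protein and crosslinked 72 hours later, and the labels list an HNRPA2B1 antibody. There were 2 libraries of this 1 group, and no control immunoprecipitation, input or untransfected library was analysed here. Nothing in the labels says whether the 2 libraries came from separate cultures, so the spread between them may be technical.

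Per the submitters' processing notes, the genome build was hg18 and Bowtie was used, with no version. The peak caller, its threshold, read filtering, removal of duplicate reads and the handling of reads that match several places are not given in the sources used here. Each deposited file lists regions as chromosome, start and end with a class mark of 1 for real and 0 for random. The deposited files used here give no read count, height, p-value, score or strand with a region, so the read depth behind a region is unknown from them and no region carries an error of its own. Each library had its own file, and 74 of the 1839 overlapping pairs of regions had identical coordinates in both.

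Every random entry held the same chromosome, start and end as a real region of the same library (2153 of 2153 in replicate 1 and 2266 of 2266 in replicate 2). The random class therefore gave no background in position, and the comparisons of real with random regions planned before the data were examined could not be made from coordinates. Real regions were compared instead with the same regions moved to random positions on their chromosome, within the span the lists cover, in 100 draws (seed 20). This background was planned as an alternative for the overlap of the libraries. It ignores that RNA comes only from transcribed sequence, so it is a background for chance position alone. A further background, chosen after seeing the data, shifted all regions of a chromosome together by 1 random offset of at least 1000000 bases, or 25% of the span where the span is short, which keeps their clustering.

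The annotation at hand was on GRCh38, and no hg18 genome or annotation was used here. Coordinates were not converted between builds. Planned comparisons of strand, annotation class, motif content, base composition, peak height and gene lists (hnRNP, SR splicing factor, ribosomal protein, histone, nuclear long noncoding RNA, small RNA, mesenchymal, luminal epithelial, cell cycle, cytoskeleton, and chromatin and RNA helicase genes) were not made, and the gene of the precipitated protein was not located. Positions are given as in the files, on hg18. The files do not say whether starts count from 0 or 1, so the length of a region is its end minus its start.

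Overlap of at least 1 base between libraries was found with bedtools 2.31.1. Shares have 95% Wilson intervals, which cover counting error over listed regions only. Regions are not biological replicates, and tests on them compare these 2 lists. Fisher exact tests on regions also take neighbouring regions as independent although many lie in clusters, so their p-values may be too small. Chromosomes were compared between libraries with two-sided Fisher exact tests and Benjamini-Hochberg adjustment over 24 chromosomes, at an adjusted p threshold of 0.05. Comparisons of region counts between libraries, by chromosome or by cluster, treated the lists as independent. Most regions are shared, which by itself makes these tests conservative, and a lack of calls does not show equal shares. Regions of both libraries at most 10000 bases apart were joined into clusters. The regions named individually are the 25 overlapping pairs with the longest overlap between libraries, a rule fixed before the data were examined. Clusters and chromosomes were picked for description after their values were seen. Spacings of regions were compared between clusters holding at least 15 regions in each library, by the longest run of region midpoints whose spacings of up to 5000 bases agreed within 25 bases. That run was set against 10000 shuffles of the spacings.

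The steps were tested on simulated data. Sets of 2153 regions made to share 50% of their members gave an overlap of 50.0%. With both lists drawn as independent counts, the chromosome test called chromosome 1, raised 1.6-fold, in 99% of 100 simulations. It called 16 of 2300 unchanged chromosomes. Only chromosome 1, which holds the most regions, was raised, and the real lists share most of their regions. These rates therefore do not carry over to other chromosomes or to the real lists. The spacing test found 100% of 50 inverted copies and called 8% of 50 unrelated pairs at an unadjusted p below 0.05. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0. Alternatives tried were other overlap minimums, the longer 50% of regions, regions found in both libraries, other clustering distances and each library alone.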

Results

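HNRPA2B1, an RNA-binding protein of the heterogeneous nuclear ribonucleoprotein family, was precipitated from crosslinked MDA-MB-231 cells in 2 replicate libraries. Replicate 1 listed 2153 regions covering 453 kb, and replicate 2 listed 2266 regions covering 481 kb. Without a control library, a listed region is a call and is not by itself shown to be bound. Both lists held regions on 24 chromosomes, 1 to 22, X and Y, and 0 regions on the mitochondrial chromosome. The median region length was 151 bases in replicate 1 (quartiles 112 and 224) and 152 bases in replicate 2 (quartiles 112 and 227). Lengths ran from 99 bases in both lists to 7030 bases in replicate 1 and 7029 bases in replicate 2. Listed regions never overlapped within a library, and the smallest gap between neighbours was 101 bases in both. Read counts behind the regions are unknown, so binding strength was not compared.

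The first comparison asked whether the 2 libraries marked the same places. Of the replicate 1 regions, 1831 of 2153 were overlapped by a replicate 2 region by at least 1 base, which is 85.0% (95% Wilson interval 83.5% to 86.5%). Of the replicate 2 regions, 1816 of 2266 were overlapped, which is 80.1% (78.4% to 81.7%). Regions moved to random positions on the same chromosome were overlapped in 0.034% ± 0.042 (SD over 100 draws) of cases for replicate 1, and in at most 0.139% in any draw. The permutation p was 0.0099 in each direction, the smallest that 100 draws can give. Overlapping stretches summed to 388 kb, or 85.6% of the bases of replicate 1 and 80.6% of those of replicate 2. Among the 1839 overlapping pairs, the starts differed by a median of 4 bases and the ends by a median of 4 bases. Both edges lay within 5 bases in 641 pairs (34.9%), and 74 pairs (4.02%) had identical coordinates.

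The longest regions lay on chromosome 11. The region at 65023102 to 65030132 in replicate 1 was 7030 bases long and recurred in replicate 2 at 65023103 to 65030132, an overlap of 7029 bases. The next longest overlaps, of 3715 and 2946 bases, lay at 64965845 to 64969560 and at 64946861 to 64949811 on the same chromosome (replicate 1 coordinates). Both belong to a cluster from 64946861 to 64969566 that held 18 regions in each library. Regions covered 81.6% of that 22.7 kb cluster in replicate 1 and 82.3% in replicate 2. Another cluster on chromosome 11, from 62041214 to 62057599, held 20 regions in replicate 1 and 23 in replicate 2. They covered 64.2% and 68.0% of its 16.4 kb. In all, 12 of the 25 pairs with the longest overlap were on chromosome 11, all of them in the clusters named above or the region of 7030 bases. A region can enter more than 1 pair. The replicate 1 region at 62054144 to 62056185 overlapped different replicate 2 regions by 978 and 959 bases. Chromosome 11 held 14.2% of the listed bases of replicate 1 and 13.3% of those of replicate 2, against 8.64% and 7.77% of the regions.

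**Figure D1:**
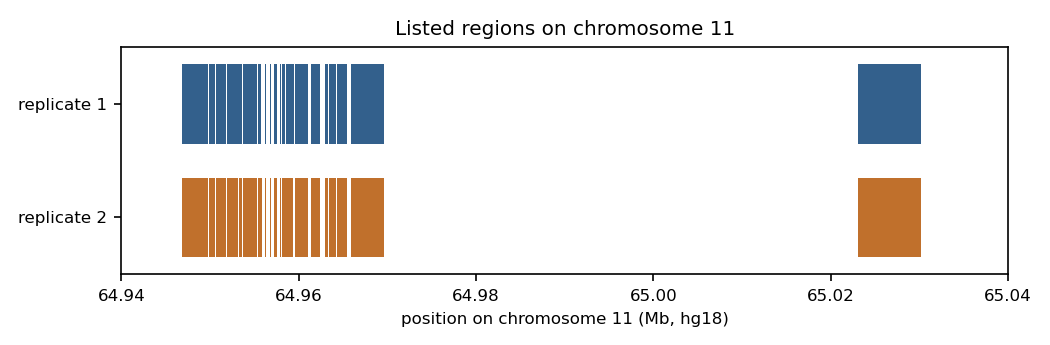
Listed regions of replicate 1 (upper row) and replicate 2 (lower row) around these regions of chromosome 11 (horizontal axis, position in Mb on hg18). Each block is 1 region drawn to scale. The cluster from 64946861 to 64969566 held 18 regions in each library, and the single block to its right is the region of 7030 bases in replicate 1 and 7029 in replicate 2.

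The other 13 of the 25 pairs were spread over 10 chromosomes. Chromosome 14 held 3 of them, with overlaps of 2341 bases at 104766983 to 104769325, 1254 bases at 38719568 to 38720822 and 1130 bases at 104770453 to 104771583 (replicate 1 coordinates here and for the regions that follow). A pair of regions on chromosome 10, at 91055750 to 91057394 and 91088477 to 91089450, overlapped their counterparts by 1640 and 968 bases. Single regions followed on chromosome 17 at 105118 to 107358 (2238 bases of overlap), chromosome 2 at 132728350 to 132730194 (1844 bases), and chromosome 16 at 33870013 to 33871736 (1723 bases). The region of chromosome 9 at 134884663 to 134886305 overlapped by 1641 bases. On chromosome 19, the region at 54068444 to 54069932 had the same coordinates in both libraries and was 1488 bases long. The pair on chromosome 12 differed in length, with 1256 bases at 123962185 to 123963441 in replicate 1 and 2020 bases at 123962172 to 123964192 in replicate 2. The list ended with a region of chromosome 7 at 22517157 to 22518169 (1012 bases of overlap) and one of chromosome 1 at 177342337 to 177343270 (933 bases). These 25 overlaps held 43.7 kb, or 11.3% of the bases shared by the libraries, while the median overlap over all pairs was 151 bases.

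Listed regions lay close together. In replicate 1, 833 of 2153 regions (38.7%, interval 36.7% to 40.8%) had another region within 1000 bases, against 0.246% ± 0.165 (SD over 100 draws) of regions moved at random. In replicate 2 these were 859 of 2266 (37.9%, interval 35.9% to 39.9%) against 0.238% ± 0.147. The permutation p was 0.0099 in each library, the smallest possible with 100 draws. Transcribed sequence is itself unevenly spread, and the moved regions do not allow for that. Joining regions of both libraries at most 10000 bases apart gave 1287 clusters, of which 943 held regions of both libraries, 151 of replicate 1 only and 193 of replicate 2 only.

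The clusters with the most regions were 2 on chromosome 2. The one from 87536299 to 87601257 held 46 regions in replicate 1 and 51 in replicate 2, and the one from 111896633 to 111968901 held 36 and 42. A cluster on chromosome 6, from 36672555 to 36731509, held 32 in each library. On chromosome 1, the cluster from 142870279 to 142935527 held 23 and 27 regions, and that from 144024718 to 144080753 held 20 and 23. Clusters on chromosome 8 (119111160 to 119158768, 20 and 20 regions), chromosome 7 (130377965 to 130440146, 18 and 21) and chromosome 4 (177903093 to 177950109, 20 and 18) followed. Regions covered little of these long clusters, with 15.6% and 20.4% of the span in the first cluster of chromosome 2 and 4.76% and 6.26% in the first of chromosome 1. Some shorter clusters were filled more densely. On chromosome 14, regions covered 56.4% of the 10.6 kb from 104766977 to 104777582 in replicate 1 and 71.8% in replicate 2. The cluster of chromosome 11 from 122433479 to 122436607 was covered to 49.3% and 52.0%, and that of chromosome 6 from 44325111 to 44329491 to 43.0% and 40.3%. The 20 clusters with at least 10 regions in each library held 17.8% of the regions of replicate 1 and 18.2% of those of replicate 2. For 44 clusters with at least 12 regions in total, shares of regions were compared by Fisher exact tests that treat the lists as independent. After Benjamini-Hochberg adjustment 0 clusters were called different between libraries, and 1 had an unadjusted p below 0.05. That one, on chromosome 1 from 146617838 to 146690189, held 6 regions in replicate 1 and 18 in replicate 2 (Fisher exact test, unadjusted p = 0.023, adjusted p = 1).

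Chromosomes 1, 6 and 11 held the most regions in replicate 1, with 252, 227 and 186, and chromosomes 1, 6 and 2 in replicate 2, with 317, 221 and 205. The share of regions on a chromosome differed between libraries on 0 of 24 chromosomes after adjustment (Fisher exact test), and 1 chromosome had an unadjusted p below 0.05. This was chromosome 1, with 11.7% of the regions of replicate 1 and 14.0% of those of replicate 2 (Fisher exact test, adjusted p = 0.42). The test treats the lists as independent although most regions are shared, which by itself makes it conservative. The 0 calls therefore do not show that the shares were equal. The share of replicate 2 regions overlapped by replicate 1 did stand apart on 5 chromosomes when each was set against all others. By Fisher exact tests it was lower on chromosome 20 (65.4%, adjusted p = 0.013), chromosome 8 (66.1%, adjusted p = 0.0033), chromosome 2 (69.8%, adjusted p = 0.0033) and chromosome 1 (73.8%, adjusted p = 0.018). It was higher on chromosome 6 (86.9%, Fisher exact test, adjusted p = 0.036). In the other direction, again by Fisher exact tests, replicate 1 regions were overlapped by replicate 2 more often on chromosome 2 (93.8%, adjusted p = 0.0068) and chromosome 1 (92.9%, adjusted p = 0.0025). By the same exact test they were overlapped less often on chromosome 21 (65.1%, adjusted p = 0.0068) and chromosome 3 (73.0%, adjusted p = 0.020). Chromosomes 20 and 8 had high shares too (94.6% and 92.9%) but were not called (Fisher exact test, adjusted p = 0.11 for each). All these tests of overlapped shares took regions as independent although many lie in clusters, so their p-values may be too small. With clusters holding replicate 2 regions counted once, a cluster was shared if it held any replicate 1 region, overlapping or not. Only chromosome 2 then stayed past the threshold, with fewer units and a looser rule of sharing. With the longer 50% of the replicate 2 regions no chromosome did (0 of 24).

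**Figure D2:**
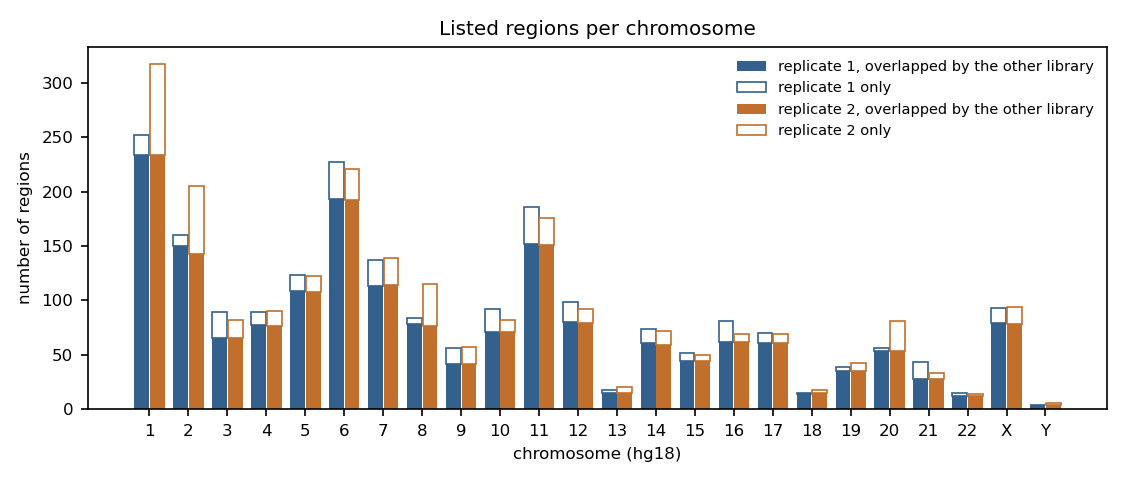
Number of listed regions (vertical axis) on each chromosome (horizontal axis, hg18) for replicate 1 (blue) and replicate 2 (orange). Filled parts are regions overlapped by the other library and open parts are regions of 1 library only. On chromosome 20, replicate 1 had 3 such regions and replicate 2 had 28, while on chromosome 21 replicate 1 had 15 and replicate 2 had 5.

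Sharing between the libraries rose with region length. In the shortest 20% of regions (99 to 108 bases in replicate 1), 66.2% of regions were overlapped by the other library, against 97.7% in the longest 20% (253 bases and more). In replicate 2 these were 52.2% (99 to 107 bases) and 94.9% (255 bases and more). At lengths of 99 or 100 bases, 54.8% of the 208 regions of replicate 1 and 45.4% of the 229 regions of replicate 2 were shared. Longer regions were shared in 88.3% and 84.0% of cases (Fisher exact test, two-sided, p = 6.2e-29 and 1.4e-35). The 322 regions of replicate 1 alone had a median length of 111 bases and the 450 of replicate 2 alone one of 108 bases. Of these, 46.3% in replicate 1 and 52.4% in replicate 2 lay within 10000 bases of a shared region, against means of 0.807% and 0.644% over 20 draws of random positions. Random positions do not allow for the uneven spread of transcribed sequence. Of all regions, 65.7% in replicate 1 and 66.0% in replicate 2 had another region of their own library within 10000 bases, a related but different measure. The library-only regions are therefore not shown to lie unusually close to shared ones.

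**Figure D3:**
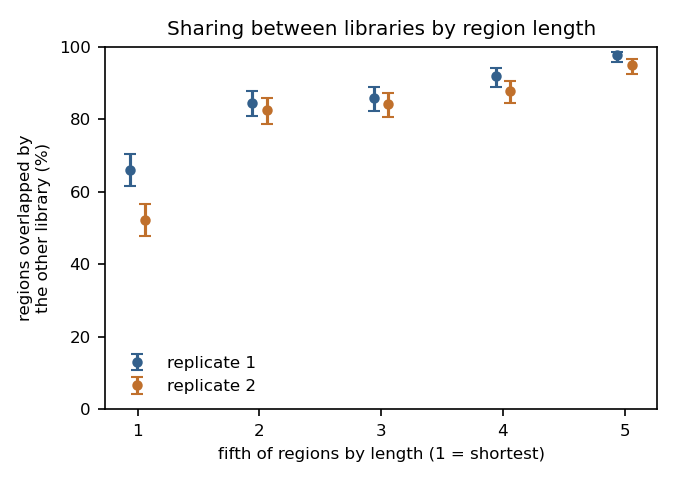
Percent of regions overlapped by the other library (vertical axis) for 5 classes of regions by length, each of about 20% of a list (horizontal axis, 1 is the shortest), in replicate 1 (blue) and replicate 2 (orange). Bars are 95% Wilson intervals. The shortest class was shared in 66.2% and 52.2% of cases and the longest in 97.7% and 94.9%.

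The length ratio of shared regions between the libraries also differed among chromosomes (permutation test over 1778 singly matched pairs, p = 1e-05, the smallest that 100000 draws can give). This permutation treated neighbouring pairs as independent although many regions lie in clusters. The p does not allow for pairs of 1 cluster varying together and may be too small. On chromosome 8, where 39 regions were of replicate 2 only and 6 of replicate 1 only, the shared regions of replicate 2 had on average 112% of the length of their replicate 1 counterparts (geometric mean over 74 pairs). On chromosome 2, with 62 and 10 such regions, they had 110% of the length over 137 pairs. On chromosome 16, with 7 of replicate 2 only and 19 of replicate 1 only, they had 90.7% of the length over 62 pairs. Both measures had the same sign on 16 of 23 chromosomes (Y left out). On chromosome 21, with 5 of replicate 2 only and 15 of replicate 1 only, they had 99.1% of the length over 28 pairs. On chromosome 13, with 5 of replicate 2 only and 3 of replicate 1 only, they had 93.6% over 15 pairs.

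**Figure D4:**
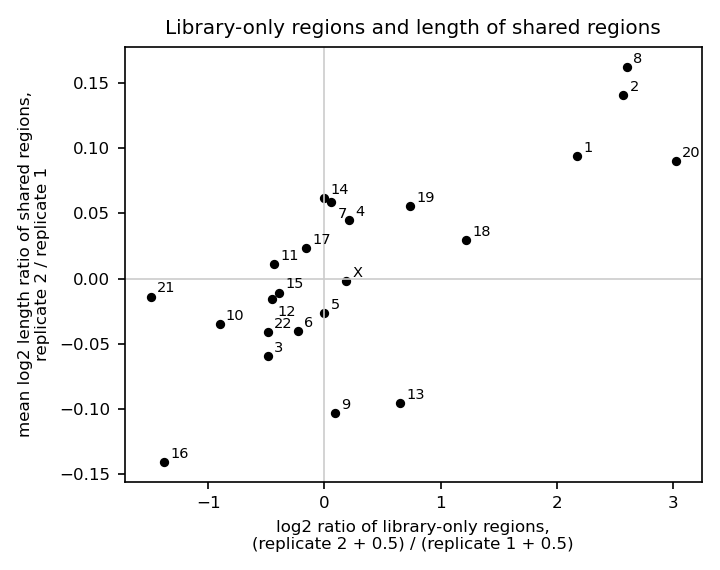
Each point is a chromosome (Y left out, 23 points). The horizontal axis is the log2 ratio of library-only regions, replicate 2 over replicate 1 with 0.5 added to each, and the vertical axis is the mean log2 length ratio of shared regions. Chromosomes 1, 2, 8 and 20 lie at the upper right, with horizontal values of 2.17, 2.57, 2.60 and 3.03.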

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

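The overlap of replicate 1 by replicate 2 kept its side of the random background under each alternative run, between 80.0% (at least 50% of each region) and 89.0% (within 1000 bases), and was 80.1% with replicate 2 as the query. The share of regions with a neighbour within 1000 bases was 38.3% as a mean of both libraries, 37.9% without replicate 1 and 38.7% without replicate 2. It was 65.8% within 10000 bases, 33.5% for the longer 50% of regions and 37.5% for regions found in both libraries, each above random positions. Within 100 bases it was 0%, below random positions, because the smallest gap in the lists is 101 bases. The median length was 151.5 bases as a mean of both libraries, 152 without replicate 1 and 151 without replicate 2. It was 226 for the longer 50%, by construction, and 161.5 for regions found in both libraries. The count of chromosomes called for a differing share of regions between libraries was 0 in each setting run, by the same test that treats the lists as independent. The 5 chromosomes whose overlapped share stood apart became 1 with clusters counted once and 0 with the longer 50% of replicate 2 regions, and the cause was not tested. Both settings have fewer units, and clusters counted once use a looser rule of sharing, so these counts are not like for like. With at least 50% of each region the same 5 chromosomes were called, and within 1000 bases chromosome 16 was added, giving 6. With replicate 1 as the query 4 were called: 3 and 21 as lower, and 1 and 2 as higher, while 6, 8 and 20 were not called. Chromosomes 20 (94.6% of 56 regions) and 8 (92.9% of 84) had shares like those of 2 (93.8% of 160) and 1 (92.9% of 252), with fewer regions. The higher share on chromosomes 1 and 2 is the other side of their lower share in replicate 2. There replicate 2 listed 317 and 205 regions against 252 and 160 in replicate 1, with similar numbers overlapped. Merging regions within a library changed nothing, since none overlapped. The settings planned for strand, annotation, motifs, base composition, peak height and gene lists were not run, nor was leaving out a library possible where the 2 are compared. No paired analysis was possible because there is 1 group. The unknown read depth limits what a region missing from 1 list shows: it was not listed there, which is not absence of binding.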

Other observations

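The tests on heterogeneity over all library-only regions, on region length and on mirrored spacing were chosen after the patterns had been seen, while the tests on position within a chromosome, on the length of shared regions and on single regions were written down before their results but after the pattern itself had been seen. Chromosome Y held 4 regions in replicate 1 and 6 in replicate 2. All 4 of replicate 1 lay between 10644904 and 10647936 and were overlapped in replicate 2. The other 2 regions of replicate 2, at 3065096 to 3065196 and at 4272772 to 4272871, were 100 and 99 bases long. How reads that match several places were handled is not given. A region listed on chromosome Y therefore does not show that the bound RNA came from that chromosome.

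The libraries did not differ alike on all chromosomes. Of the 772 regions found in 1 library only, 58.3% belonged to replicate 2, but on chromosomes 1, 2, 8 and 20 replicate 2 had 83, 62, 39 and 28 against 18, 10, 6 and 3 in replicate 1. A single threshold over the genome at different depths would give a like skew everywhere, and permuting clusters over chromosomes argues against it (permutation p = 1e-05, the smallest that 100000 draws can give). A few local clusters, as joined over gaps of at most 10000 bases, are also argued against as the whole cause. The 490 regions that were the single library-only region of their cluster were uneven over chromosomes too (permutation p = 1e-05, again the smallest possible). Such a cluster may also hold shared regions. Places with wider gaps were split into several clusters, so the test does not reach local causes on a larger scale. Local clusters stay open as part of the cause. As was predicted for them beforehand, the skews of the lower and upper part of a chromosome, split at the median position of its regions, were not clearly related. Spearman rho was 0.2169 (permutation p = 0.32, adjusted p = 0.32 over 2 relations). Pearson r was 0.31 (permutation p = 0.15), and 0.12 without the 2 farthest of 23 chromosomes. The sign was the same in both parts on 11 of 23, counting chromosome 5, where both were 0. On chromosomes 1, 2, 8 and 20, picked for their skew, both parts leaned to replicate 2. Their log2 ratios were 1.63 and 2.69, 4.35 and 1.77, 4.09 and 1.40, and 3.17 and 2.63. A cause acting on whole chromosomes would make the parts related, which was not clearly seen over all 23. Counting clusters once left 1 of the 5 chromosomes called for their overlapped share. That setting has fewer units and a looser rule of sharing, so the loss of calls cannot decide this. A stringency of the calls set chromosome by chromosome is a candidate explanation, and it was predicted that shared regions would be longer where a library listed more: rho was 0.6792 across 23 chromosomes (permutation p = 0.00049, adjusted p = 0.00098), with Pearson r 0.75 (p = 6e-05) and 0.67 without the 2 farthest chromosomes. Without chromosomes 1, 2, 8 and 20 rho was 0.44 over 19 chromosomes (p = 0.059), so much of the relation rests on those 4. Skew and length ratio had the same sign on 16 of 23 chromosomes and opposite signs on 9, 11, 13, 17 and X, while the skew was 0 on chromosomes 5 and 14. A real difference in RNA or chromosome copies between the libraries would predict the same and stays open, untested.

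Regions found in 1 library only were short. Regions of 99 or 100 bases had odds of being shared of 0.161 relative to longer ones in replicate 1 and 0.158 in replicate 2. These odds restate the pattern and cannot test whether such regions passed in 1 library by a small margin, and the lists hold no read counts that would show a margin. No biological explanation was tested, as both libraries are of 1 group.

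The 2 clusters with the most regions, both on chromosome 2, may be near-identical copies in inverted order that take the same reads. The longest run of matching spacings with one cluster inverted was 7 regions in each library, against a median of 4 with shuffled spacings. Shuffles reached runs of up to 9 regions in replicate 1 and 8 in replicate 2. Without inversion the run was 6 regions in replicate 1 and 4 in replicate 2, against the same median of 4. Among 132 cluster pairs and orientations per library this pair, inverted, ranked first in both at a tolerance of 25 bases. By shuffled spacings the adjusted p was 0.343 in replicate 1 and 0.554 in replicate 2 (unadjusted 0.0026 and 0.0042). The libraries share most of their regions, so the rank in replicate 2 is not independent of that in replicate 1. With a tolerance of 50 bases the run was 9 and 11 regions, with adjusted p of 0.29 and 0.026. With a tolerance of 10 bases the pair ranked first in replicate 1 only (run of 5 regions, permutation test, adjusted p = 0.94), and in replicate 2 a pair on chromosomes 11 and 7 ranked first (run of 3 regions, adjusted p = 1). The test therefore leaves the question open, and the sequence of both places would decide it.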
